A study of Homo sapiens with 6 samples.

How the data were processed

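Total RNA from 6 clones of U2OS, a human osteosarcoma cell line, was measured on Illumina bead arrays, 1 array per clone. Per the labels, 3 clones were controls and 3 were MBTD1 knockout clones made with CRISPR/Cas9, and the cells were grown untreated in serum-containing medium. The sample titles name the controls "control KO" and the labels call them control clones, while the design text speaks of wild-type cells. How the controls were derived is not described further. Nothing in the labels says whether the clones were grown, extracted or hybridised on different days, so p-values measure the spread between these 6 arrays. The arrays' slides are not given in the sources used here.

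The authors deposited a table of 34694 rows with the mean bead intensity of each array on a linear scale, neither background-subtracted nor normalized. Beside it stand a detection p-value, which per the file headers compares the signal with background beads, the standard error of the bead signals and the mean number of beads. The deposited rows are genes, not probes: fractional bead numbers show that several probes of a gene had been averaged. A separate deposited table holds log2 values. They equalled a quantile normalization of the log2 intensities of the same rows to within 4.99e-09, with a median of 6.4256 on every array, so their scale and direction are known. The submitters' processing notes list lumi and limma without versions or roles; the software that summarised the arrays is not given in the sources used here. Every column was matched to its clone by the sample number in the labels, and 0 other columns of per-sample values were present.

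Of the deposited rows, 92 are spike-in controls, of which 0 to 3 per array reached a detection p under 0.05; they were left out of all tests. In 27 rows the gene name had been turned into a date, and the name was restored from the description in the same row. The median intensity was between 84.7 and 87.2 on the 6 arrays, with a median of 20 to 22 beads behind each value. Between 12982 and 13511 rows per array, 37.5% to 39.1%, were above background at a detection p under 0.05. The number of arrays limits the precision of every comparison.

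The values analysed were made from the intensities with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8). Background was corrected with the normexp model, an offset of 16 was added, and log2 values were quantile normalized. The planned model takes the background from detection p-values. The default fit on all rows gave a background SD of 114 to 164 intensity units. Detection p-values of averaged rows do not mark a single probe's place among the 770 negative controls, so the fit was restricted to the 27408 rows (79.0%) whose detection p was a whole multiple of one step on all 6 arrays, within a tolerance of 0.001 of a step. On these the background mean was 81.7 to 84.2 and its SD 3.08 to 3.77. The restriction was conceived on reading the table, before any test, but it was adopted after the default fit had been run and had called 0 genes. Counts of genes past the threshold come from the restricted fit unless another setting is named.

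A gene was tested if its detection p was under 0.05 on at least 3 of the 6 arrays, which left 13145 genes and excluded 21457. Knockout and control were compared with limma (lmFit and eBayes, 2-sided) without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences are knockout minus control on the log2 scale. An exact permutation test was added for MBTD1; with 3 against 3 arrays the smallest p it can give is 0.1. Because each row is already a gene, counts of probes and of genes coincide, and the planned choice between a gene's probes did not arise.

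Gene lists were fixed before the data were examined. Of 22 lists, 21 had at least 5 tested members and were tested with camera, limma's competitive set test, at an inter-gene correlation of 0.01 and again with an estimated correlation, each adjusted over the lists. They cover the TIP60/NuA4 partners of MBTD1, MBT domain and polycomb genes, HOX genes, homologous recombination, end joining, p53 targets, S phase, G2/M, histones, ribosomal proteins, MYC targets, oxidative phosphorylation, glycolysis and hypoxia, lipid synthesis, ATF4 and unfolded protein response, NF-kB, interferon, immediate early genes, matrix, osteoblast lineage, and epithelial, blood and endothelial markers. The mean shift of a list is the mean log2 difference of its tested members minus the mean over all tested genes in the same setting. Chromosome arms and bands are not in the files, so shifts were tested per chromosome, over 23 chromosomes. The neighbours of MBTD1 within 1 Mb were found with the GRCh38.p14 gene table, used only for gene names, for which genes lie next to each other and for gene span.

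Genes were named by a rule fixed in advance: MBTD1; the 12 largest rises and 12 largest falls past the threshold with groups that did not overlap, leaving out provisional and open-reading-frame symbols, which were only counted; up to 4 members of each list with the smallest p; and neighbours of MBTD1. Genes named outside this rule are marked as chosen after their values were seen.

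A short-gene score per array was defined after the data had been seen. It is the median centred log2 value of 1034 tested genes spanning up to 4 kb minus that of 2660 genes spanning over 64 kb. Spans were found for 97.6% of tested genes with plain symbols and for 78.5% of all tested genes, so the score speaks for plain symbols. Spans are genomic and not transcript lengths.

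The fit was tested on simulated data with the real means and spreads, 200 of the 13145 genes being changed in each of 20 runs. In the knockout against control comparison it recovered 39.4% of genes changed 1.49-fold, 96.4% of those changed 2-fold and 99.8% of those changed 4-fold, and 6.61% of the calls were false. The list test found a shift of 0.3 in 20 of 20 runs, with 3 calls of lists that had not been shifted. Simulated values were drawn independently for every gene and array, whereas the real lists are correlated, at an estimated 0.433 for ribosomal protein genes. These rates therefore do not give the error rates where genes move together, as in the real data.

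Alternatives were the authors' values, no background correction, scaling to a common median, cyclic loess, an offset of 50, other detection filters, eBayes with trend and robust settings, array weights, an adjusted p threshold of 0.01, the clone number as a block and leaving out each array. The default background fit on all rows, which follows the planned model, was run first and became an alternative once the restricted fit was adopted. The short-gene score as a covariate was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.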

Results

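Gene expression was profiled in 3 control clones and 3 MBTD1 knockout clones of U2OS osteosarcoma cells to ask how loss of MBTD1 alters the transcriptome. MBTD1 is a reader of methylated histone tails that belongs to the TIP60/NuA4 acetyltransferase complex. Each clone was measured on 1 array. The sample titles name the controls "control KO" and the labels call them clones, while the design text calls them wild-type cells. Whether the 3 controls are independent clones is therefore not known. Between 12982 and 13511 genes per array lay above background, and 13145 genes were tested.

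MBTD1 itself gave a low signal in every clone. Its log2 level was 5.06 ± 0.01 (SD, n = 3) in control clones and 4.93 ± 0.28 (n = 3) in knockout clones, a difference of -0.13 with a standard error of 0.15. The knockout clones measured 5.17, 4.99 and 4.62. The difference was within the spread between clones (exact permutation p = 0.7, 2-sided, smallest possible 0.1; limma adjusted p = 0.676). Its bead numbers were fractional, 25.5 in control 1 and 18.5 in knockout 2, so several probes had been averaged. Genome editing need not lower a transcript. Where the probes lie relative to the edited part is not given in the sources used here, so this measurement checks nothing about the edit.

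**Figure D1:**
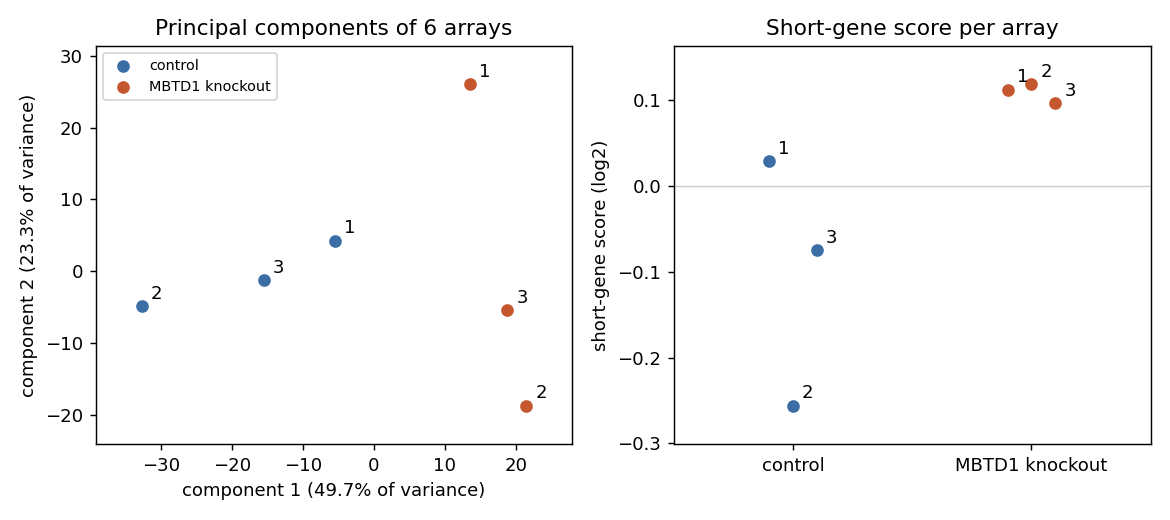
Left, the 6 arrays on the first 2 principal components of the tested genes, with clone numbers. Right, the short-gene score of each array in log2 units; the knockout clones lie between 0.0966 and 0.118, and control 2 lies lowest at -0.256.

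The clones separated by genotype on the first principal component, which held 49.7% of the variance. Control clones lay at -5.53, -32.7 and -15.6, and knockout clones at 13.5, 21.5 and 18.9. Spread was wider among knockout clones: their mean variance per gene was 1.77 times that of the controls, a ratio that compares clones with clones only if the controls are independent clones. Pearson correlations across genes were 0.983 to 0.993 between control clones, 0.975 to 0.984 between knockout clones and 0.960 to 0.984 between the groups. Control 1 and control 2 differed at least 2-fold in 150 genes, while control 3 differed from them in 8 and 5 genes. From knockout clones 1 to 3, control 1 differed at least 2-fold in 136, 230 and 151 genes. For control 2 these counts were 664, 765 and 696, and for control 3 they were 274, 335 and 262. Control 1 was thus about as far from knockout clones 1 and 3 as from control 2, and control 2 was the array farthest from the knockout clones. The short-gene score separated the groups and also the controls, at 0.0285, -0.256 and -0.0749 in control clones and 0.112, 0.118 and 0.0966 in knockout clones.

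Among genes without provisional or open-reading-frame names, the largest rise in knockout clones was that of NDUFA3, a subunit of respiratory complex I, which rose 4.55-fold, from 7.17 ± 0.51 to 9.36 ± 0.26 (log2 mean ± SD, n = 3 each; limma adjusted p = 0.00764). SNORA12, a small nucleolar RNA, rose 4.54-fold from 5.51 ± 0.22 to 7.70 ± 0.75, and SNHG9, a small nucleolar RNA host gene, rose 4.46-fold from 6.23 ± 0.30 to 8.38 ± 0.25. HIST1H4C, a histone H4 gene, rose 4.45-fold from 10.01 ± 0.37 to 12.16 ± 0.15 (limma adjusted p = 0.00352). ATP5I and ATP5E, small subunits of ATP synthase, rose 3.45-fold and 3.07-fold, and NDUFA1 of complex I rose 2.94-fold. ATP5I reached a detection p under 0.05 in 1 of 3 control clones, at control values of 7.30, 6.56 and 6.83. S100A6, a calcium-binding protein, rose 3.29-fold, and ROMO1, a mitochondrial membrane protein, rose 3.10-fold. TCEB2, which encodes elongin B, rose 3.01-fold. IFI27L2 rose 2.98-fold and DPM3, a subunit of dolichol-phosphate mannose synthase, rose 2.95-fold. Most of these genes also differed between control clones: control 1 lay above control 2 by 1.02 for NDUFA3, by 1.07 for ROMO1 and by 1.12 for ATP5E on the log2 scale, against 0.51 for SNHG9 and 0.35 for SNORA12.

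The largest falls were in GTSF1, a germline factor of small RNA silencing, ANXA10 and COL16A1. GTSF1 fell 5.34-fold, from 7.14 ± 0.19 to 4.72 ± 0.35 (n = 3 each; limma adjusted p = 0.00352), and was above background in 2 of 3 knockout clones. ANXA10, an annexin, fell 4.12-fold from 6.51 ± 0.19 to 4.46 ± 0.20 and remained above background in 1 of 3 knockout clones. COL16A1, a collagen chain, fell 3.44-fold from 7.51 ± 0.13 to 5.73 ± 0.24. MFAP5, a microfibril protein, fell 2.88-fold, and GPC5, a cell-surface proteoglycan above background in 1 of 3 knockout clones, fell 2.41-fold. RHOBTB3 fell 2.59-fold, the transcription factor SOX18 2.39-fold and the zinc finger gene ZFP82 2.34-fold. GLO1, a glyoxalase, fell 2.06-fold, CCND3, which encodes cyclin D3, 2.02-fold, CTNNAL1 2.00-fold and TRIML2 1.90-fold. ZFP82 and TRIML2 were above background in 2 of 3 knockout clones. Control 1 and control 2 differed by 0.34 for GTSF1, 0.24 for ANXA10 and -0.002 for COL16A1, but by -0.83 for RHOBTB3, -0.84 for GLO1 and -0.79 for CTNNAL1.

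**Figure D2:**
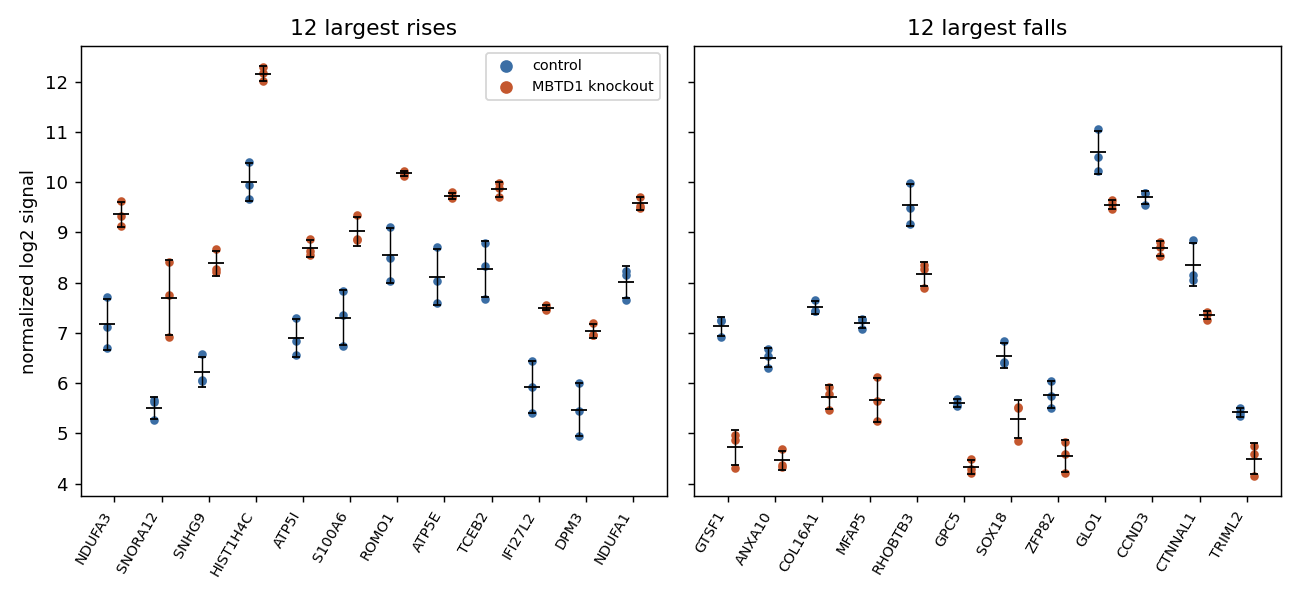
Normalized log2 signal of the 12 named genes with the largest rises and the 12 with the largest falls, 1 point per clone, with bars for the mean and SD of 3 clones. The groups do not overlap in any of the genes; NDUFA3 rises from 7.17 to 9.36 and GTSF1 falls from 7.14 to 4.72.

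In all, 207 of 13145 genes (1.57%) passed the threshold with limma, 158 higher and 49 lower in knockout clones. Of these, 116 changed at least 2-fold, 105 higher and 11 lower. Scaling to a common median called 344 higher and 48 lower, and cyclic loess 249 higher and 39 lower. Of the 158 higher genes, 76 have provisional or open-reading-frame names; 67 of these begin with LOC, and 21 of the LOC genes are described as like a ribosomal protein, and their values are uncertain because near-identical copies can share signal. In 3405 tested genes (25.9%) the groups did not overlap, against 10% by chance on average over all splits. Where genes move together, the share in 1 split can lie far from 10%, so the excess does not measure an effect of genotype. At an unadjusted p under 0.05 there were 2682 genes, 1323 higher and 1359 lower. The count depended on single choices: limma's default background fit on all rows called 0 genes, with 2260 at an unadjusted p under 0.05, and leaving out control 3 called 0, with 1919. Leaving out control 1 called 578, control 2 50, knockout 2 50 and knockout 3 51 genes.

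**Figure D3:**
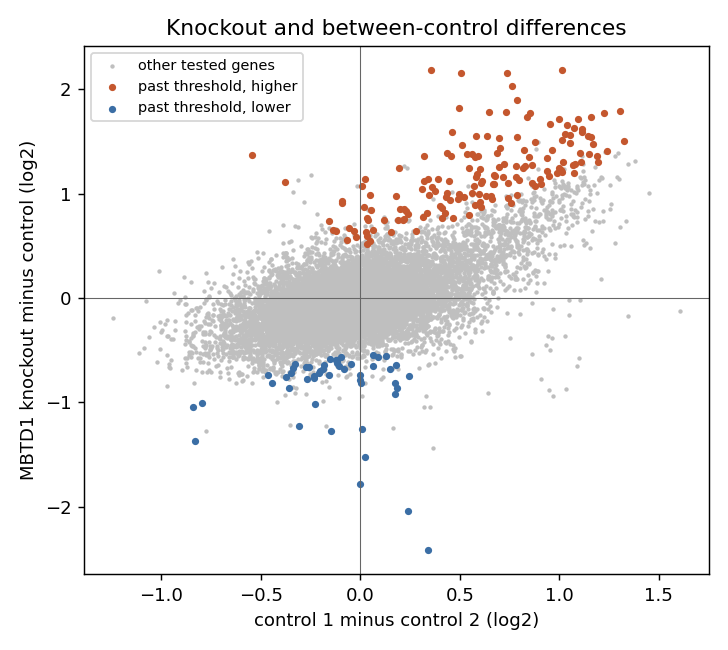
For each tested gene, the log2 difference between knockout and control clones against the difference between control 1 and control 2. The 158 higher genes have a median between-control difference of 0.604 and the 49 lower genes of -0.122.

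Cytosolic ribosomal protein genes and nuclear-encoded genes of oxidative phosphorylation were higher as groups. Of 73 tested ribosomal protein genes, 9 rose, 0 fell and 64 did not pass; adjusted over the list alone, 34 rose and 1 fell. RPS28 rose 2.57-fold, RPS27 2.55-fold, RPL39 2.26-fold and RPL37A 2.00-fold. The list's median difference was 0.38 (camera adjusted p = 1.69e-12), and its adjusted p = 0.811 with an estimated correlation. Of 46 oxidative phosphorylation genes, NDUFA1, COX7B and UQCRQ rose 2.94-fold, 2.13-fold and 2.14-fold, while SDHB, a subunit of succinate dehydrogenase, fell 1.48-fold; adjusted over the list alone, 17 rose and 7 fell. The list's median was 0.25 (camera adjusted p = 0.00163), and its adjusted p = 0.811 with an estimated correlation. The size of both shifts depended on the scaling. The mean shift, relative to all tested genes, was 0.411 for the ribosomal list, 0.56 with cyclic loess and 0.732 after scaling to a common median. For the oxidative phosphorylation list it was 0.318, 0.396 and 0.477. Without control 2 the mean shift was 0.29 for the ribosomal list and 0.21 for the oxidative phosphorylation list, and without control 1 0.508 and 0.416. Control 1 exceeded control 2 by a median of 0.475 over the ribosomal list and 0.481 over the oxidative phosphorylation list. With the short-gene score as a covariate the camera adjusted p was 0.0949 for ribosomal protein genes and 0.929 for oxidative phosphorylation genes.

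Interferon-stimulated genes were higher as a group. Of 20 tested, IFITM3, which restricts virus entry, rose 2.42-fold from 7.36 ± 0.43 to 8.63 ± 0.32 (n = 3 each; limma adjusted p = 0.0410) and 19 did not pass; adjusted over the list alone, 5 rose and 0 fell. PSMB8, IFITM2 and ISG20 differed by 0.64, 0.99 and 1.07 on the log2 scale without passing. The list's median was 0.21 (camera adjusted p = 0.00109), and its adjusted p = 0.811 with an estimated correlation. Control 1 exceeded control 2 by a median of 0.0546 over this list, but by 0.86 for IFITM3, 1.04 for IFITM2 and 0.54 for ISG20, against 0.03 for PSMB8. With the short-gene score as a covariate the mean shift of this list went from 0.326 to 0.206 (camera adjusted p = 0.0295).

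Genes of S phase and MYC targets with ribosome biogenesis genes were lower as groups, with 0 members passing over all genes in either. The 32 S phase genes had a median of -0.27 (camera adjusted p = 0.00355), with 26 negative and 6 positive, and 0 passed adjusted over the list alone. This list's adjusted p = 0.826 with an estimated correlation, 0.126 after scaling to a common median, 0.135 without knockout 1 and 0.508 with the short-gene score as a covariate. RRM1 and RRM2, subunits of ribonucleotide reductase, differed by -0.57 and -0.68. Over the 30 MYC and ribosome biogenesis genes the median was -0.26 (camera adjusted p = 0.00109); adjusted over the list alone, 7 fell and 1 rose. This list's adjusted p = 0.811 with an estimated correlation, and with the short-gene score as a covariate its mean shift went from -0.255 to -0.198 (camera adjusted p = 0.00633). BOP1 and WDR12, assembly factors of the large ribosomal subunit, differed by -0.93 and -0.60, and the chaperonin HSPD1 by -0.57 while its partner HSPE1 differed by 0.76. Between control 1 and control 2 the median difference was -0.237 for S phase genes and -0.0788 for MYC targets. The named members differed more between these controls, each in the direction of its knockout difference. Control 1 minus control 2 was -0.56 for RRM1, -0.40 for RRM2, -0.38 for BOP1, -0.38 for WDR12, -0.28 for HSPD1 and 0.42 for HSPE1.

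Partners of MBTD1 in the TIP60/NuA4 complex gave 0 calls. Of 16 tested, 0 changed over all genes or adjusted over the list alone, 12 differences were negative and 4 positive, and the median was -0.13 (camera adjusted p = 0.0968). The list was lower in 19 of 19 processing settings, the one reported included, and passed in 2, without a filter (camera adjusted p = 0.042) and without control 1 (camera adjusted p = 0.038). All settings draw on the same 6 arrays, and over them the camera adjusted p reached 0.929. With an estimated correlation the camera adjusted p was 0.811. Control 1 lay below control 2 here too, with a median difference of -0.19 over the list. MORF4L2, DMAP1, C20orf20 and YEATS4 had the smallest p, with log2 differences of -0.60, -0.35, -0.38 and -0.35. For these genes control 1 minus control 2 was -0.70, 0.07, -0.28 and -0.23. Among 29 MBT domain and polycomb genes, CBX6, a polycomb chromobox protein, fell 1.58-fold and 28 did not pass (camera adjusted p = 0.541; adjusted over the list alone 0 rose and 2 fell). Of 20 HOX genes 0 passed (camera adjusted p = 0.516).

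DNA repair genes gave 0 calls over all genes. The 19 tested homologous recombination genes had a median of -0.05 (camera adjusted p = 0.753), and the 17 end joining genes, which include the 53BP1 pathway, a median of -0.15 (camera adjusted p = 0.0585; adjusted over the list alone 0 rose and 1 fell). The end joining list passed in 5 of 19 settings, with a camera adjusted p between 0.00914 without a filter and 0.417 with a detection p under 0.01 required on all 6 arrays, and was lower in all 19. RNF8, a ubiquitin ligase of the damage response, measured 1.40-fold lower without passing (limma adjusted p = 0.0723). Its log2 difference was -0.49 with a standard error of 0.12. It was above background in 0 of 3 knockout clones, so its level there is uncertain. Of 25 p53 targets, C12orf5, which encodes the fructose bisphosphatase TIGAR, fell 1.68-fold and 24 did not pass (camera adjusted p = 0.199); CDKN1A, an inhibitor of cyclin-dependent kinases, differed by -0.56. The mean shift of the p53 list was -0.14, but -0.227 without knockout 1 (camera adjusted p = 0.025) and -0.0181 without knockout 2 (camera adjusted p = 0.892).

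In the remaining lists, 1 gene each passed among histones, immediate early genes and matrix genes. HIST1H4C rose among 20 histone genes (camera adjusted p = 0.0585; adjusted over the list alone 2 rose), whose control 1 values exceeded control 2 by a median of 0.359. The mean shift of the histone list was 0.699 without knockout 1 (camera adjusted p = 5.42e-08) and 0.0214 without knockout 2 (camera adjusted p = 0.892, camera direction lower). HIST1H4C itself measured 12.01, 12.30 and 12.17 in knockout clones 1 to 3. DUSP1, a phosphatase of MAP kinases, fell 1.82-fold among 21 immediate early genes (camera adjusted p = 0.333), and FBN2, a fibrillin, fell 1.59-fold among 39 matrix genes (camera adjusted p = 0.756). Camera adjusted p was 0.101 for 31 G2/M genes, 0.984 for 24 glycolysis and hypoxia genes, 0.753 for 26 lipid synthesis genes, 0.333 for 24 ATF4 targets, 0.333 for 17 NF-kB genes and 0.568 for 13 osteoblast genes, with 0 genes passing in each. Some of these lists passed when 1 array was left out: G2/M genes without control 1 (camera adjusted p = 0.0178) or knockout 3 (0.0187), ATF4 targets without knockout 1 (0.0392), and glycolysis and hypoxia genes (0.00419) and NF-kB genes (0.0204) without knockout 2. The mean shift of the NF-kB list was 0.0997, and -0.0527 without knockout 1. Markers of other cell types gave 0 calls among 4 epithelial genes, too few for camera, and among 6 blood and endothelial genes (camera adjusted p = 0.756).

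Genes next to MBTD1 on chromosome 17 did not pass the test. Of 25 genes within 1 Mb, 17 were tested and 0 passed, with a median difference of 0.328; 13 differences were positive and 4 negative. At an unadjusted p under 0.05 in limma 8 were higher and 0 lower, against 1323 higher and 1359 lower among all 13145 tested genes. Over the whole of chromosome 17 the median difference was 0.0465. NME2, a nucleoside diphosphate kinase, differed by 0.61 (limma adjusted p = 0.126), EME1, a subunit of a structure-specific endonuclease, by 0.44 (0.0896), XYLT2 by 0.49 (0.1075), MRPL27 by 0.60 (0.135) and UTP18 by -0.48 (0.285). Control 1 minus control 2 was 0.77 for NME2, 0.04 for EME1, 0.49 for XYLT2, 0.82 for MRPL27 and -0.28 for UTP18.

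Over whole chromosomes the shifts were small. Genes of chromosomes 4, 5 and 8 were lower, with medians of -0.10, -0.09 and -0.11 (camera adjusted p = 0.0287, 0.0287 and 0.00997), and genes of chromosome 19 were higher, with a median of 0.05 (camera adjusted p = 0.00997). Over the same chromosomes the medians of control 1 were -0.0357, -0.0473, -0.0397 and 0.0301 and those of control 2 0.0561, 0.0441, 0.0294 and -0.0438, each relative to the mean of the control clones.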

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

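The default background fit on all rows follows the planned model and had called 0 genes before the restricted fit was adopted. The short-gene score as a covariate was added after the data had been seen, and the other alternatives were planned. The number of genes past the threshold depended on the setting. Where the cause of a moved count is not given, the cause was not tested. Slide as a block and the mean of a gene's probes could not be run, since neither slides nor probes are in the table. Near background, signal limits what can be called: 21457 genes were not tested.

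Genes past the threshold numbered 64 (44 higher, 20 lower, 25 at least 2-fold) with the authors' values and the same without background correction, 61 (42, 19, 27) with an offset of 50, and 26 (22, 4) at an adjusted p under 0.01. They numbered 392 (344 higher, 239 at least 2-fold) after common median scaling, 288 (249 higher) with cyclic loess and 304 (243 higher) with trend and robust eBayes. Without a filter 4 passed (1 higher, 3 lower, 3 at least 2-fold) among 34602 tested, and with the strict filter 361 (280, 81) among 8244. Array weights gave 1391 (811 higher, 580 lower, 181 at least 2-fold). The default background fit and the score covariate each gave 0 (0 higher, 0 lower, 0 at least 2-fold), with 2260 and 638 genes at an unadjusted p under 0.05 in limma.

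Leaving out each array in turn gave 0 to 578 genes, 0 to 463 higher, 0 to 115 lower and 0 to 281 at least 2-fold, 5 to 8 lists, 1 to 7 chromosomes and 0 to 1 neighbours of MBTD1. Lists past the threshold numbered 8 without a filter, 2 with the score covariate and 0 with an estimated correlation. Chromosomes numbered 8 after median scaling, 0 without a filter, 2 with array weights, 2 with the default background fit and 1 with the score. With array weights 2 neighbours passed. Without knockout 2 the glycolysis and hypoxia response list passed as higher (mean shift 0.299, camera adjusted p = 0.00419), against a mean shift of 0.0217 with all 6 arrays. Over the fits that leave out an array its mean shift lay between -0.217 and 0.299.

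Clone numbers do not pair the arrays: deviations of same-numbered clones correlated at 0.0656, 0.0153 and 0.0187. With the clone number as a block 122 genes passed (108 higher, 14 lower), 101 of them shared with the 207, and 5 lists.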

Other observations

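The tests of the short-gene axis, of shared signal, of mixed RNA and of gene counts over other splits were chosen after the results had been seen; those of chromosome segments, of germline genes and of list and chromosome counts over other splits were written before theirs. The gene families in the next paragraph, and every gene named in it, were chosen after their values were seen.

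All 5 tested metallothionein genes, which bind zinc and copper, had positive differences, with a median of 1.22; only MT1X passed, rising 2.60-fold. Control 1 exceeded control 2 by a median of 1.06 over these genes. Of 10 tested host genes of small nucleolar RNAs and related noncoding RNAs, SNHG9, SNHG6, SNHG5 and RPPH1 rose, and over the list 6 differences were positive and 4 negative. Control 1 exceeded control 2 by a median of 0.239 over this list. For SNHG9, SNHG6, SNHG5 and RPPH1 it did so by 0.51, 1.32, 0.55 and 0.34, against knockout differences of 2.16, 1.51, 0.79 and 0.99. Knockout clones differed strongly from one another in GAGE genes, a cancer-testis family on the X chromosome whose members share sequence: GAGE12G measured 10.81, 4.27 and 6.07 in knockout clones 1 to 3 against 7.93 ± 0.48 (SD, n = 3) in controls. Outside this family, CA9 measured 7.24, 4.17 and 5.40, and BNIP3 9.45, 6.58 and 8.97, in the knockout clones, against 4.47 ± 0.17 and 8.70 ± 0.14 in controls. An SD over 0.5 was found in 474 tested genes among knockout clones and 185 among control clones.

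Over the 119 tested ribosomal protein and respiratory chain genes, whose mean difference was positive, knockout minus control 3 correlated with control 1 minus control 2, which shares no array with it (Pearson r = 0.731 across genes, which are not independent; permutation p = 1e-04, the smallest that 10000 permutations can give); with control 1 or control 2 in the place of control 3, r was 0.409 and 0.749. Over all tested genes the 3 arrangements gave 0.525, 0.255 and 0.397. With a short-gene score made without these genes as a covariate, 18.3% of their mean difference stayed (95% bootstrap interval 2.75 to 29.3). The mean difference went from 0.375 to 0.0685 and the mean standard error from 0.167 to 0.2. The bootstrap intervals here and below resample genes with the 6 arrays held fixed, so they leave out the spread between clones. Signal shared with gene copies was left open (respiratory chain median 0.255, interval 0.0744 to 0.565). A candidate explanation is therefore a difference in recovery or labelling of short transcripts between RNA samples, but the score also separates the genotypes, so an effect of MBTD1 on these genes stays open and was not tested apart from it.

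Whether the 49 lower genes lie off this axis was not settled. Control 1 lay below control 2 in 33 of them, and above control 2 in 147 of the 158 higher genes. The median of control 1 minus control 2 was -0.122 over the lower and 0.604 over the higher genes. That median was also negative over all tested genes spanning over 16 kb, between -0.125 and -0.0617 by span class. The 33 genes alone therefore do not place the lower genes on the axis. With the score as a covariate 80.2% of the lower genes' median difference stayed (interval 75.5 to 97.1), against 61.8% for the higher genes (56.4 to 65.6). In that fit 0 genes passed. Loss of a chromosome segment is argued against for the 11 genes that fell at least 2-fold taken as a set, not for each gene. The median over them of their nearest tested genes' medians was -0.14 (interval -0.206 to -0.0397), above the bound of -0.3 set in advance. Each gene had 20 such neighbours, except SOX18 with 12. Neighbour medians ran from -0.218 for SOX18 to 0.109 for GTSF1, and 1 median over all of them cannot exclude a loss at a single gene. A separate hypothesis was that germline genes fell together with GTSF1. The 28 tested cancer-testis and germline genes outside the GAGE family had a median of 0.03 and a camera direction of higher, not lower (camera adjusted p = 0.111 over the 4 lists added here, 0.0832 before adjustment); with GAGE genes included the 41 genes gave an adjusted p = 0.235. That the lower genes, led by GTSF1, ANXA10 and COL16A1, respond to MBTD1 loss remains a hypothesis, since small clonal deletions or a founder shared by the knockout clones could give the same values and were not tested.

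Control 3 lay between control 1 and control 2, and the number of calls rests on it. Among 2286 bright genes its spread around the best mixture of both was 1.73 times the bead error, against 1.89 for control 1 and 2.34 for control 2 set against the other controls, and 2.68 to 3.17 for each knockout clone set between the other 2. RNA of the other control clones in this array cannot be told apart from a clone of intermediate state, because 1 array is set against technical noise. Without control 3, 0 genes passed.

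The 6 arrays can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split called 207 genes and the highest other split 0, so 1 of 10 splits gave as many; for genes at least 2-fold changed the counts were 116 and 0, again 1 of 10. At an unadjusted p under 0.05 the real split gave 2682 genes and the highest other 811. List calls behaved differently: the real split called 5 lists, 8 of 10 splits called as many, and the highest other called 10. For chromosomes the real split called 4, 6 of 10 splits called as many, and the highest other called 6. A preset correlation of 0.01 thus called lists and chromosomes in groupings that mix the genotypes.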
